A study of Gossypium hirsutum with 12 samples.

How the data were processed

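Total RNA from leaves of upland cotton (Gossypium hirsutum, labelled CCRI 12) was measured on a 1-colour cotton gene expression array from Agilent, in which each sample is labelled with the dye Cy3 and hybridised alone. The 12 arrays fall into 4 groups of 3, taken from the sample titles: control and transgenic plants at 25 days and at 45 days. Per the labels, the transgenic plants constitutively expressed the second RNA recognition motif (RRM) domain of FCA from Brassica napus, an RNA-binding protein that promotes flowering. The series text states 3 biological replications without saying which plants went into each, so the p-values measure the spread between these samples. It names TRIzol for the RNA, whereas the labels' protocols name an RNeasy kit, and this difference was not resolved.

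The spot intensity of each array was background-subtracted and detrended within the array by Agilent Feature Extraction, per the file headers, with surrogate values for signals that were not above background and no normalization between arrays. The version was 10.7.1.1 per the file headers and the series text, and 10.5.1.1 per the submitters' processing notes. The deposited series table holds log2 values for 27005 of the 43603 probes. All 27005 were well above background on at least 1 array, which also held for 8224 of the other 16598 probes, so the rule that chose them stays unknown. Column medians of that table lay between 9.79 and 9.80. Each column correlated with its own array's log2 signal at 0.987 or more, so the direction is that of the signals, while the normalization behind the table is not given in the sources used here.

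From the scanner files, log2 of the processed signal was taken for 43803 non-control spots per array and the array's 75th percentile over those spots was subtracted. Control spots and spots marked as non-uniform or population outliers were left out, between 8 and 166 spots per array. Spots of the same probe, 5 for each of 50 probes, were averaged on the log2 scale. Probes well above background on at least 3 of the 12 arrays, whatever their group, were tested: 31185 of 43603. Outlier removal left 371 of 374220 values missing. A total of 31185 probes were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 4 group means, eBayes with an intensity trend, 8 residual degrees of freedom before moderation). The tests were two-sided, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05. Counts with at least a 2-fold change as well are given separately. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

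The 5 comparisons were transgenic against control at 25 days and at 45 days, the difference between these effects, and 45 against 25 days within each genotype. The comparisons, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. Genes were named by this rule: among passing probes whose arrays of the groups compared did not overlap, the 10 with the largest rise and the 10 with the largest fall whose description names a gene product, and, for each list and each transgenic comparison, up to 4 passing probes with the largest change. Every probe named for FCA was to be reported, and 0 were found. Most probes carry no product name, so whether any probe measures the inserted domain or cotton FCA is not known.

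Of the probe descriptions, 5177 name a gene product, 15950 read unknown, 13369 give only an EST library and 8325 only a genome scaffold. These names are the array design's best sequence matches, some to organisms far from plants. A RefSeq gene table of 99454 rows matched 0 probe identifiers, and with no genome given, no position is stated for any probe. Lists were matched to the descriptions that name a product. That restriction was made after the data were seen, because the fibre pattern otherwise matched EST library names, and the unrestricted matching was run as an alternative.

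The 32 lists covered flowering time and MADS-box regulators; circadian clock and light signalling; cell wall loosening; cellulose and arabinogalactan synthesis; lignin; flavonoids; gossypol and terpenoids; the cell cycle; the cytoskeleton; ribosomal proteins; RNA binding; the photosynthetic light reactions; carbon fixation; starch and sucrose; auxin; gibberellin and brassinosteroid; ethylene; jasmonate; abscisic acid; defence; chaperones; redox enzymes; lipids; aquaporins and vacuolar transport; senescence; nutrition; plastid-encoded transcripts; FCA; and markers of seed, vascular tissue, fibre and trichome, and pollen and flower. The 28 lists with at least 5 measured probes were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative and with fry, which asks whether a list's own probes move on balance in a single direction.

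The arrays lay on 3 slides of 4 arrays, each slide scanned together. Slide 1 held the 3 control arrays of 45 days and transgenic 45-day replicate 1. Slide 2 held transgenic 45-day replicates 2 and 3 with control 25-day replicates 1 and 2. Slide 3 held control 25-day replicate 3 with the 3 transgenic 25-day arrays. With slide as a block, the transgenic effect equals the comparison within slide 3 at 25 days (3 transgenic arrays, 1 control) and within slide 1 at 45 days (1 transgenic array, 3 controls). No slide held both ages of a genotype. With slide as a block, age in control leaves is therefore joined across slides 1 and 2 through the transgenic 45-day arrays. Age in transgenic leaves is joined across slides 2 and 3 through the control 25-day arrays.

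A probe not well above background on any array of a group has only a bound there, as has a saturated probe. Its change is given as at least N-fold, the brighter group's mean over the dimmer group's mean, with each dim array taken at the higher of the probe's own signal and the lowest signal among that array's spots well above background. A probe with 5 spots counted as well above background where any of them was. Between 61.3% and 70.5% of spots per array were well above background, and the small number of arrays limits the precision.

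The fit was tested on simulated data made from 30831 probes with 200 changed. A log2 change of 1 was recovered for 50.7% of the changed probes at 25 days, 49.3% at 45 days, 22.4% for the difference of effects, and 59.7% for age in each genotype. A log2 change of 2 was recovered for 78.8%, 81.8%, 63.6%, 81.8% and 90.9% in the same order, and a log2 change of 0.5 for 8.96%, 2.99%, 1.49%, 13.4% and 5.97%. The number of unchanged probes called was 8, 9, 2, 5 and 5. A list moved as a whole was found in each simulation, and 0 of 20 random lists were called. The simulated probes varied independently, so this does not show how often camera calls lists whose members vary together. The requirement on recovered probes was relaxed to these measures after its first run, in which dim and noisy probes limited recovery.

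Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes well above background, no filter and a filter of all 12 arrays, outlier spots kept, the deposited log2 values, fits of the compared groups alone, no intensity trend, array weights, slide or scan as a block, a replicate block, and each replicate left out. Spots of control type and unmatched probes were not analysed here.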

Results

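Leaf transcript levels were compared between wild-type cotton and cotton carrying a constitutively expressed RNA-binding domain of rapeseed FCA, the series' question being whether this domain affects cell size and fibre length. Each of 4 groups, control and transgenic plants at each of 25 and 45 days, was measured on 3 arrays. Between 61.3% and 70.5% of the spots on an array were well above background, and the 75th percentile of the intensity lay between 984 and 1957. Replicates of a group correlated at 0.973 to 0.988 across probes, and 0 of these replicate pairs held identical values. Pairs of arrays from different groups were not checked for identical values. Age separated the arrays along the first principal component, which held 66.8% of the variance, and the second component, with 7.47%, placed the 3 transgenic 45-day arrays at the opposite end from the 3 control 45-day arrays. All log2 fold changes below are from limma, with the standard error after ±, over 3 arrays per group.

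In 25-day leaves, 50 probes differed between transgenic and control plants with arrays weighted equally, and 2494 with array weights. The largest rise among probes with a gene name was at a probe named Wsv453, after a protein of white spot syndrome virus, at 9.71 ± 0.37 (adjusted p = 1.42e-07), where 1 of 3 control arrays was above background. Glucose-6-phosphate 1-dehydrogenase, the entry enzyme of the oxidative pentose phosphate pathway, fell, with a log2 fold change of -1.38 ± 0.14 (adjusted p = 0.00193). Both probes for the vacuolar H+-pyrophosphatase, a proton pump of the vacuole membrane, that passed the test fell, at -0.84 ± 0.12 (adjusted p = 0.0193) and -0.82 ± 0.13 (adjusted p = 0.0343). Among probes without a gene name, A_08_P014756 was at least 481-fold higher in transgenic leaves and A_08_P345492 at least 320-fold higher, while A_08_P002356 was at least 268-fold lower and A_08_P007666 at least 64.4-fold lower. These 4 unnamed probes were chosen after their values were seen.

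At 25 days, 50 of 31185 probes passed, 21 higher and 29 lower, with a median change of 1.40 in size on the log2 scale, and 37 of them changed at least 2-fold. Only 4 of the 50 carry the name of a gene product, and all 4 are named above. At an unadjusted p under 0.05 there were 2360 probes. Within slide 3, which held 3 transgenic arrays and 1 control array, all of them among the 6 compared, the 50 had a median change of 1.52 in size, and 12 probes passed, 8 of them among the 50. Wsv453 passed there (adjusted p = 1.80e-05), at least 331-fold higher than on the control array, where it was not well above background, whereas glucose-6-phosphate 1-dehydrogenase (-1.45, adjusted p = 0.0908) and the vacuolar H+-pyrophosphatase probes (-0.86 and -0.92, adjusted p = 0.333 and 0.277) did not. Both pyrophosphatase probes also lost the call without any 1 control replicate, without transgenic replicate 3, with normexp, with the 25-day arrays fitted alone and with a replicate block, the last also for glucose-6-phosphate 1-dehydrogenase. The count was 22 with a replicate block, 154 without transgenic replicate 1, 18 without transgenic replicate 3, and 19 without control replicate 1 or control replicate 3.

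Camera called 0 of 28 gene lists at 25 days over all arrays, but 7 without transgenic replicate 1, 3 without control replicate 2 or transgenic replicate 3, and 2 with a filter of all 12 arrays. Over all arrays there were 6 lists at an unadjusted p under 0.05, and fry and camera with an estimated correlation also called 0. The smallest adjusted p was 0.0868, shared by flowering regulators (median log2 fold change -0.14), chaperones (0.09) and fibre and trichome markers (0.12). Of the lists, aquaporins and vacuolar transport alone had members that passed, 0 higher and 2 lower of 25 measured, the pyrophosphatase probes named above, against a list median of 0.08 (adjusted p = 0.322). Adjusted over the list alone, 2 lipid genes were higher and 3 lower of 78, 1 flowering regulator was lower of 18, 1 gossypol gene was lower of 12, 2 photosynthetic genes were lower of 46, and 1 pollen and flower gene was higher of 2 measured. Median, mean and test differed in sign for the circadian, gossypol, photosynthetic, ethylene, jasmonate, abscisic acid and defence lists, none of which was called.

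In 45-day leaves, 4094 probes differed between transgenic and control plants, and of 117 measured probes for ribosomal proteins 65 were lower and 2 higher in transgenic leaves, with a median log2 fold change of -0.70. Camera called this list, as it did those of the cell cycle, chaperones, wall loosening and starch and sucrose, but all 5 calls were lost with an estimated correlation between members. The rise at Wsv453 was again the largest among named probes, at least 253-fold (adjusted p = 4.02e-07). Nicotinate-nucleotide pyrophosphorylase, an enzyme of NAD synthesis, was at least 3.25-fold lower (adjusted p = 0.00725). Sucrose-phosphate synthase, which makes the precursor of sucrose, rose by 1.17 ± 0.18 (adjusted p = 0.00516).

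A total of 4094 probes passed at 45 days, 13.1% of those tested, with 2259 higher and 1835 lower. The median change was 0.66 in size on the log2 scale, 701 probes changed at least 2-fold (274 higher, 427 lower), and 490 of the 4094 name a gene product. Within slide 1, which held 1 transgenic array and 3 control arrays, again among the 6 compared, the 4094 had a median change of 0.74 in size, and 132 probes passed, 122 of them among the 4094. The standard error there had a median of 0.277, against 0.187 over all arrays, and 5 of the 88 probes named for this comparison passed. The count fell to 675 without transgenic replicate 1, the transgenic array on slide 1, to 2122 without control replicate 3, and to 276 when the 45-day arrays were fitted alone.

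**Figure D1:**
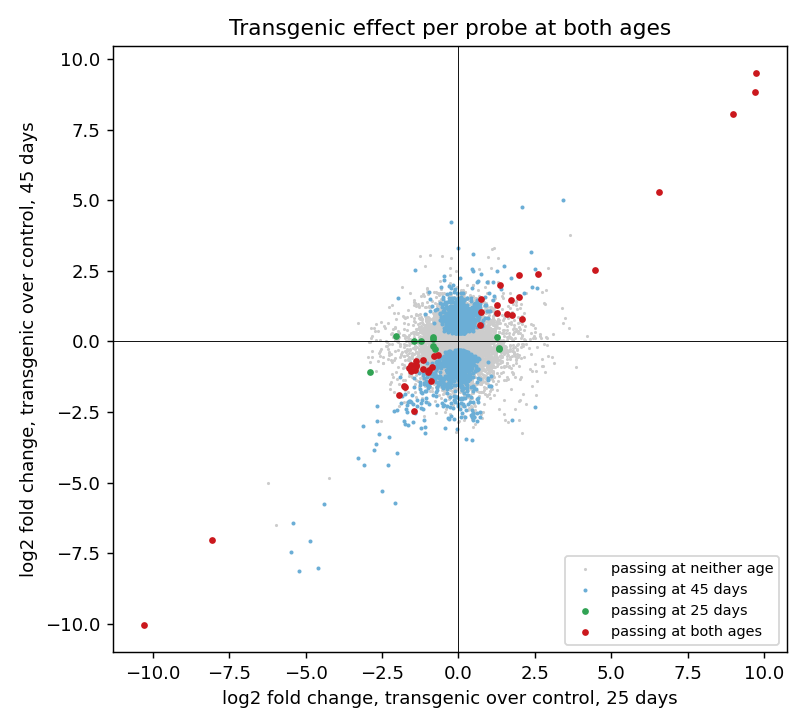
Log2 fold change of transgenic against control leaves at 25 days (horizontal axis) and at 45 days (vertical axis), 1 point per tested probe, with probes that passed at either age or at both marked by colour. The values correlate at 0.143 across probes, and the probes far from 0 on both axes lie in the same direction at both ages.

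Among the other named probes with the largest fitted rises at 45 days, the protein induced upon tuberization was at least 3.46-fold higher in transgenic leaves, sulfite oxidase at least 4.41-fold, and Bax inhibitor 1, a suppressor of cell death, at least 1.04-fold (above background on 2 of 3 transgenic arrays). A (+)-delta-cadinene synthase probe, for the first committed step of gossypol synthesis, rose by 3.31 ± 0.74, with 1 of 3 control arrays above background. The iron-sulfur subunit of the cytochrome b6-f complex rose by 1.87 ± 0.47, a ZIM motif protein by 1.59 ± 0.18 (adjusted p = 0.00179) and a dehydration-induced protein like RD22 by 1.44 ± 0.40. An alpha tubulin probe was at least 1.77-fold higher and acetyl-CoA carboxylase, the first enzyme of fatty acid synthesis, at least 1.34-fold, the latter above background on 1 of 3 transgenic arrays. Of these, the ZIM motif protein also passed within slide 1 (1.73, adjusted p = 0.0463).

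Large fitted falls at 45 days were found for cytochrome P450 71A9 (-3.23 ± 0.44), the protein ATFP2 (-2.74 ± 0.74), a Cys-3-His zinc finger protein (-2.47 ± 0.48) and alcohol dehydrogenase 2b (at least 2.78-fold). Alcohol dehydrogenase 2b also passed within slide 1 (at least 3.45-fold, adjusted p = 0.0237), where the transgenic array was not well above background, and it did not pass with normexp background correction. Serpin, a protease inhibitor, fell with a log2 fold change of -3.46 ± 0.97, calmodulin, a calcium sensor, with -2.42 ± 0.52, a probe named for MSHA biogenesis protein MshO with -2.66 ± 0.78, and laccase, an oxidase of lignin polymerization, with -2.41 ± 0.53. Each of these was above background on 1 of 3 transgenic arrays, and laccase did not pass with normexp. With normexp, alcohol dehydrogenase 2b was at 0.19 and laccase at 0.0867, where the median of all probes was 0.24, so neither showed a clear fall there. A fall of -3.04 ± 0.85 for 2-deoxyribose-5-phosphate aldolase, also above background on 1 of 3 transgenic arrays, was -0.56 within slide 1.

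Camera called 5 of 28 lists at 45 days, 1 up and 4 down, and 0 with an estimated correlation, while fry called 3. The ribosomal list fell most clearly (adjusted p = 4.35e-17; adjusted p = 0.794 with an estimated correlation; 0.0263 by fry), with 75 lower and 6 higher adjusted over the list alone. Its median was -0.74 within slide 1, where 88 of 117 members were below 0, which rests on transgenic replicate 1 alone. The ribosomal proteins with the largest falls were L33, with a log2 fold change of -2.21 ± 0.23 (adjusted p = 0.00127) at a probe that also passed within slide 1 and -1.46 ± 0.28 at another, S28 (-1.83 ± 0.33, above background on 1 of 3 transgenic arrays and 0.40 with normexp, where the median of all probes was 0.24) and S27-2 (-1.34 ± 0.16). Per array, the list's median deviation from the mean of all arrays was -0.54, -0.46 and -0.60 on the 45-day transgenic arrays, and -0.11, 0.07 and 0.47 on the 45-day control arrays.

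**Figure D2:**
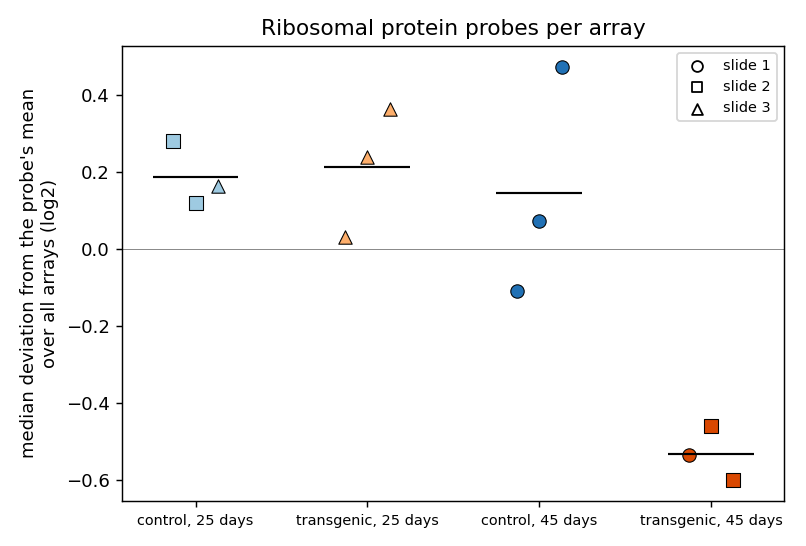
Median deviation of the 117 ribosomal protein probes from their mean over all arrays (vertical axis, log2 units) by group (horizontal axis), 1 point per array, marked by slide. The 3 transgenic 45-day arrays lie between -0.60 and -0.46, below the other 9 arrays.

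Starch and sucrose genes moved up (adjusted p = 0.00727; adjusted p = 0.549 with an estimated correlation; 0.0081 by fry), with 8 of 53 higher and 0 lower, and 10 higher and 1 lower adjusted over the list alone. Besides sucrose-phosphate synthase, 3 probes for beta-amylase, which releases maltose from starch, rose by 1.12 ± 0.26, 0.98 ± 0.25 and 0.68 ± 0.19, the first with 2 of 3 control arrays above background and the second with overlapping groups. The list's median was 0.37 over all arrays, and 0.34 within slide 1, which rests on transgenic replicate 1 alone. Cell cycle and DNA replication genes moved down with a median of -0.42 (adjusted p = 0.00214; adjusted p = 0.794 with an estimated correlation), 9 of 74 lower and 3 higher, and 20 lower and 4 higher adjusted over the list alone. The members with the largest falls were histones, the proteins that package DNA: H1-III (-1.69 ± 0.49), H4 (-1.37 ± 0.35), H2B (-1.14 ± 0.30) and H3 (-0.99 ± 0.19). Within slide 1, with 1 transgenic array, the list's median was -0.45. Per array, the groups overlapped, with median deviations of 0.14, 0.08 and 0.33 on the transgenic arrays and 0.42, 0.22 and 0.50 on the control arrays.

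Heat shock and chaperone genes moved down with a median of -0.29 (adjusted p = 0.00106; adjusted p = 0.794 with an estimated correlation), with 3 of 55 lower and 0 higher, the same adjusted over the list alone. Heat shock protein 70 fell with a log2 fold change of -2.14 ± 0.47, and 2 probes for mitochondrial chaperonin CPN60-2, which folds imported proteins, with -1.28 ± 0.29 and -0.96 ± 0.25. Within slide 1, with 1 transgenic array, the median was -0.23. Wall loosening genes moved down with a median of -0.28 (adjusted p = 0.0463; adjusted p = 0.882 with an estimated correlation), a call lost within slide 1 (-0.23, adjusted p = 0.147), with quantile normalization, without a filter, and without control replicate 1, control replicate 2 or transgenic replicate 2. A single member of 39 fell, the xyloglucan endotransglycosylase/hydrolase XTH-21, an enzyme that cuts and rejoins wall xyloglucan (-1.15 ± 0.31, with overlapping groups), and 0 passed adjusted over the list alone. By fry, chaperones and the cell cycle were both at 0.116 and wall loosening at 0.31.

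**Figure D3:**
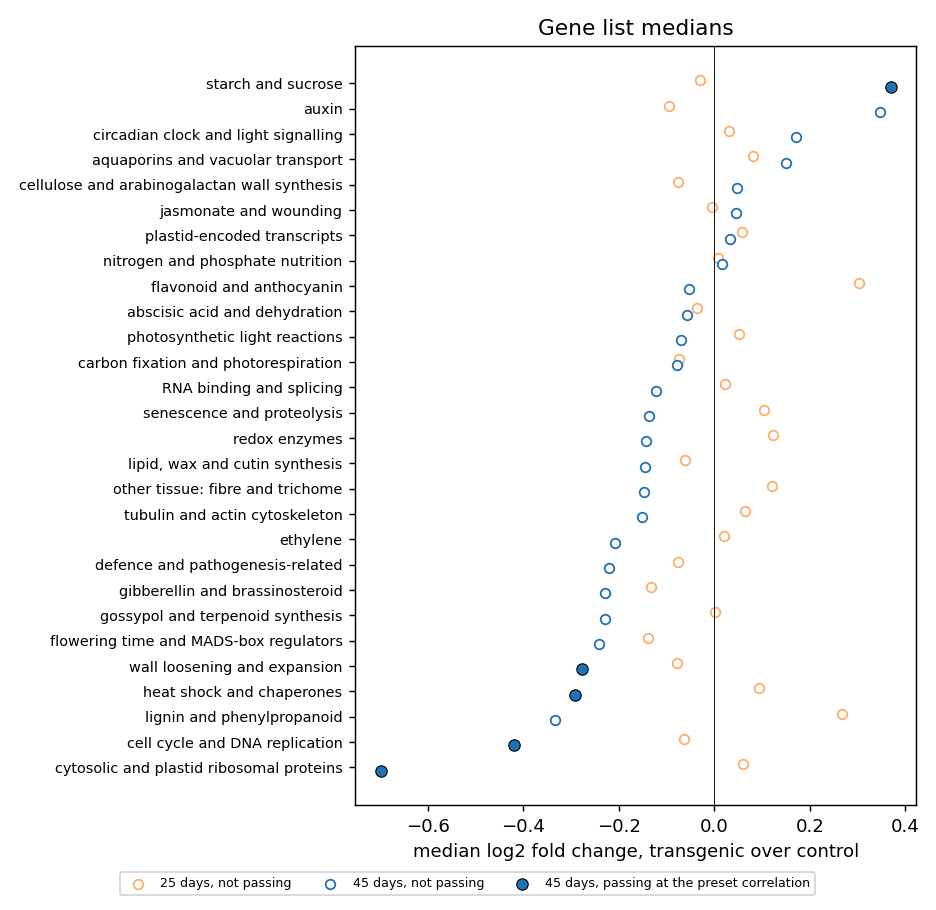
Median log2 fold change of each gene list (horizontal axis) in transgenic against control leaves at 25 and at 45 days, 1 pair of points per list (vertical axis), with filled points for lists that camera called. The ribosomal list has the lowest median at 45 days, -0.70, and the starch and sucrose list the highest called one, 0.37.

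The lists of cellulose and arabinogalactan, the cytoskeleton, fibre and trichome markers and auxin were not called at 45 days over all arrays. Cellulose and arabinogalactan genes had 2 higher and 1 lower of 69, with 0 adjusted over the list alone and a median of 0.05 (adjusted p = 0.836). A hybrid proline-rich protein fell (-1.36 ± 0.30), while a predicted proline-rich protein and a proline-rich protein rose by 0.54 ± 0.16 and 0.52 ± 0.15. Tubulin and actin genes had 1 higher and 4 lower of 63, and 1 higher and 3 lower adjusted over the list alone, at a median of -0.15 (adjusted p = 0.0502). Further probes for alpha tubulin, a subunit of microtubules, fell, with log2 fold changes of -0.98 ± 0.19, -0.64 ± 0.13 and -0.62 ± 0.12. Fibre and trichome markers had 0 members passing of 28, also adjusted over the list alone (median -0.15, adjusted p = 0.511). Auxin genes had 1 higher of 21, auxin response factor ARF3 (0.42 ± 0.13), and 0 adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0502). Within slide 1 the auxin list passed with a median of 0.40 (adjusted p = 0.0305), which rests on transgenic replicate 1 alone. Per array, the list's median deviation was 0.59, 0.69 and -0.30 on the transgenic arrays and -0.50, 0.12 and -0.20 on the control arrays, and its adjusted p with an estimated correlation was 0.794 over all arrays.

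Among flowering regulators, the group FCA belongs to, 1 of 18 rose and 2 fell, the same adjusted over the list alone (median -0.24, adjusted p = 0.338). The MADS-box protein MADS4 fell (-1.49 ± 0.24), as did ULTRAPETALA 1, a regulator of meristem size (-0.63 ± 0.16), and the red and far-red light receptor phytochrome A rose by 0.86 ± 0.22. Of 10 circadian and light genes, 2 rose, the same adjusted over the list alone: the blue light receptor phototropin (0.77 ± 0.21) and the clock regulator late elongated hypocotyl (0.57 ± 0.10), with a list median of 0.17 (adjusted p = 0.321). RNA-binding and splicing genes had 2 higher and 4 lower of 33, and 2 higher and 10 lower adjusted over the list alone, at a median of -0.12 (adjusted p = 0.15; 0.0263 by fry). Bromodomain-containing RNA-binding protein 1 rose by 0.93 ± 0.14 and also passed within slide 1 (adjusted p = 0.0468), while a probe for RNA-binding region RNP-1 fell (-0.73 ± 0.12). Of 2 probes for RNA-binding-like proteins, 1 fell (-0.61 ± 0.16) and 1 rose (0.53 ± 0.12).

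Photosynthetic light reaction genes had 2 higher and 1 lower of 46, with 0 adjusted over the list alone (median -0.07, adjusted p = 0.516). These were the cytochrome b6-f subunit, the photosystem I assembly protein ycf3 (0.56 ± 0.16) and, named for pigment synthesis, phycocyanobilin:ferredoxin oxidoreductase (-0.37 ± 0.10). Plastid-encoded transcripts had 1 higher of 10, again ycf3, and 0 adjusted over the list alone (median 0.03, adjusted p = 0.716). Carbon fixation and photorespiration genes had 3 higher and 1 lower of 25, the same adjusted over the list alone (median -0.08, adjusted p = 0.979). Both probes for the P-protein of glycine decarboxylase, a photorespiratory enzyme of mitochondria, rose (1.00 ± 0.18 and 0.95 ± 0.18), chloroplast fructose-1,6-bisphosphatase II rose by 0.50 ± 0.13 and carbonic anhydrase fell (-0.79 ± 0.14).

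Lignin and phenylpropanoid genes had 4 higher and 3 lower of 34, the same adjusted over the list alone (median -0.33, adjusted p = 0.511). Cinnamyl alcohol dehydrogenase, which makes lignin monomers, rose by 0.96 ± 0.26, and 2 probes for 4-coumarate-CoA ligase-like 9 rose by 0.75 ± 0.15 and 0.71 ± 0.15. Flavonoid genes had 2 higher and 0 lower of 40, the same adjusted over the list alone (median -0.05, adjusted p = 0.969): leucoanthocyanidin reductase 2 (1.14 ± 0.18) and chalcone synthase (0.93 ± 0.18), the entry enzyme of the pathway. Gossypol and terpenoid genes had 2 higher and 2 lower of 12, the same adjusted over the list alone (median -0.23, adjusted p = 0.604). Next to (+)-delta-cadinene synthase they were geranylgeranyl pyrophosphate synthetase (0.52 ± 0.15) and 2 probes for a farnesylated protein, which carries a prenyl group and is no terpenoid enzyme (-0.54 ± 0.14 and -0.48 ± 0.13).

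Gibberellin and brassinosteroid genes had 2 higher and 0 lower of 23, the same adjusted over the list alone (median -0.23, adjusted p = 0.511), both probes for gibberellin 20-oxidase, an enzyme of gibberellin synthesis (1.14 ± 0.28 and 0.80 ± 0.18). Ethylene genes had 3 higher and 2 lower of 38, and 3 higher and 3 lower adjusted over the list alone (median -0.21, adjusted p = 0.511). The enzyme 1-aminocyclopropane-1-carboxylate synthase fell (-2.96 ± 0.68, with overlapping groups), as did an ethylene-responsive transcription factor (-0.83 ± 0.22). An EIN3-like protein, with overlapping groups, rose by 0.62 ± 0.17 and an ethylene signaling protein by 0.56 ± 0.15. Jasmonate genes had 2 higher and 0 lower of 26, the same adjusted over the list alone (median 0.05, adjusted p = 0.836), both lipoxygenases (1.07 ± 0.27, with 2 of 3 control arrays above background, and 0.76 ± 0.14). Abscisic acid genes had 1 higher of 13, the RD22-like protein, and 0 adjusted over the list alone (median -0.06, adjusted p = 0.979). Defence genes had 1 higher of 31, a disease resistance protein with overlapping groups (0.84 ± 0.25), and 0 adjusted over the list alone (median -0.22, adjusted p = 0.338).

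Redox enzymes had 2 higher and 3 lower of 86, and 1 higher and 0 lower adjusted over the list alone (median -0.14, adjusted p = 0.244). Catalase isozyme 1, which removes hydrogen peroxide, rose by 0.85 ± 0.14 and glutaredoxin-C6 by 0.93 ± 0.23, and a glutathione S-transferase (-0.57 ± 0.16) and a thioredoxin domain protein (-0.40 ± 0.11) fell. Lipid, wax and cutin genes had 1 higher and 4 lower of 78, the same adjusted over the list alone (median -0.14, adjusted p = 0.15). Chloroplast omega-3 fatty acid desaturase fell (-0.92 ± 0.13), as did trans-2-enoyl-CoA reductase ECR2 (-0.85 ± 0.13), which acts in the elongation of very long chain fatty acids, myristoyl-ACP thioesterase fell (-0.64 ± 0.15), and stearoyl-ACP desaturase rose by 0.67 ± 0.15. Aquaporin and vacuolar transport genes had 2 higher and 1 lower of 25, the same adjusted over the list alone (median 0.15, adjusted p = 0.511). The aquaporin PIP2 fell (-0.75 ± 0.13), and 2 probes for soluble inorganic pyrophosphatase, which is no membrane transporter, rose by 0.83 ± 0.23 and 0.82 ± 0.24.

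Senescence genes had 1 higher of 17, vacuolar processing enzyme 2, a protease (0.92 ± 0.20), the same adjusted over the list alone (median -0.14, adjusted p = 0.836). Nutrition genes had 0 passing of 19, also adjusted over the list alone (median 0.02, adjusted p = 0.836). Of the lists too small to test, vascular markers had 1 lower of 3 measured at 45 days, also adjusted over the list alone, the phloem kinase PCPK1 (-0.82 ± 0.19), and pollen and flower markers 0 of 2. Seed storage genes had 0 measured of 11 on the array, and 0 probes were named for FCA. Median, mean and test differed in sign for the flavonoid, cellulose, carbon fixation, jasmonate, nutrition and abscisic acid lists, and median and mean for the untested vascular list.

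The transgenic effects at 25 and 45 days correlated at 0.143 over 31185 probes, which are not independent replicates. Since 50 probes passed at 25 days, most changes there were not told from noise. A low correlation therefore does not show that the effects were unlike. Of the 4094 probes that passed at 45 days, 43.1% had the same direction at 25 days. Of the 50 that passed at 25 days, 86% had the same direction at 45 days, among them Wsv453. Probes passing at both ages numbered 18 higher and 21 lower, with 0 in opposite directions, where independent lists would share 1.52 and 1.71. The 2 effects used different control arrays.

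The difference between the effects passed limma's test for 0 of 31185 probes, with a smallest adjusted p of 0.0517 and 6925 probes at an unadjusted p under 0.05. With slide as a block 8 probes passed, all lower at 45 days relative to 25 days, so at single probes the larger count at 45 days is not shown to be a difference between ages. The count was 1481 without control 45-day replicate 1, 860 without transgenic 45-day replicate 3, 17 without transgenic 45-day replicate 2, and 1 without control 45-day replicate 3 or transgenic 25-day replicate 1. Quantile normalization gave 747, the deposited values 763, a filter of all 12 arrays 498, normexp 30, no intensity trend 1 and array weights 4440.

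By camera, 6 of 28 lists differed in effect between the ages, with 0 of them called by fry or with an estimated correlation. The count was 3 with quantile normalization (cell cycle, tubulin and actin, and redox enzymes lost), 2 without a filter and 2 in the deposited values (the same 3 and starch and sucrose lost), and 3 without control 45-day replicate 3 (the same 3 lost). Relative to 25 days, the effect at 45 days was lower for ribosomal proteins (median -0.73), chaperones (-0.31), tubulin and actin (-0.26), cell cycle (-0.28) and redox enzymes (-0.22), and higher for starch and sucrose (0.43). For redox enzymes and for tubulin and actin, control 45-day replicate 3 stood apart, at 0.26 against -0.05 and -0.11, and at 0.51 against 0.20 and 0.03, while the 45-day transgenic arrays lay at -0.11 to -0.01 and at 0.10 to 0.27. The adjusted p with an estimated correlation was 0.706 for ribosomal proteins and chaperones, 0.598 for starch and sucrose and 0.817 for the other 3. Adjusted over the list alone, 65 ribosomal probes were lower and 1 higher, 1 cell cycle probe was lower, and 0 chaperone, tubulin, redox or starch probes passed. With slide as a block, the ribosomal (-0.80, adjusted p = 2.26e-12), chaperone and cell cycle lists were still called, the tubulin, redox and starch lists (each adjusted p = 0.0766) were not, and auxin (0.45, adjusted p = 0.00942) and lignin (-0.92, adjusted p = 0.0112) were. All these values with slide as a block rest on a single transgenic array at 45 days, replicate 1, and were tested at the preset correlation only. For the last 2, transgenic 45-day replicate 3 went the other way (auxin -0.30 against 0.59 and 0.69, lignin 0.36 against -0.52 and -0.54). Both were at adjusted p = 0.817 by camera with an estimated correlation over all arrays. Of the other lists, adjusted over the list alone, 3 circadian genes were higher, 3 lignin genes higher and 1 lower, 2 flavonoid genes higher, 3 RNA-binding genes higher and 2 lower, 2 carbon fixation genes higher and 1 lower, 2 aquaporin and vacuolar genes higher and 1 lower, and 1 fibre and trichome gene higher and 4 lower. Median, mean and test differed in sign for flowering, cellulose, photosynthetic, jasmonate, abscisic acid, aquaporin and gibberellin lists.

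Between 25 and 45 days, control leaves changed at 53.4% of the tested probes. Among the largest rises, a glycine-rich protein was at least 468-fold higher at 45 days, D6-type cyclin, a cell cycle regulator, at least 26.1-fold, and ribonucleoside-diphosphate reductase, which supplies DNA precursors, at least 11.1-fold. Histone H3.2 rose by 5.50 ± 0.37 and chlorophyll-binding protein CP29.3 by 6.19 ± 0.39. Among the largest falls, class III peroxidase pod3 was at least 173-fold lower, an osmotin-like pathogenesis-related protein had a log2 fold change of -8.15 ± 0.53, and secretory laccase was at least 14.5-fold lower. Further rises were found for a thaumatin-like protein (at least 25.7-fold), a MADS-box protein (at least 21.8-fold), a blue copper-like protein (at least 7.96-fold), L-asparaginase (5.16 ± 0.32) and a disease resistance response protein (5.06 ± 0.38).

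Other falls with age in control leaves were those of a cell wall glycine-rich protein (-6.74 ± 0.51, above background on 2 of 3 arrays at 45 days), pathogenesis-related protein class 10 (-6.68 ± 0.95) and the transcription factor NAC2 (-6.31 ± 0.59), both above background on 1 of 3 arrays at 45 days, and a hybrid proline-rich protein (at least 56.2-fold, being saturated at 25 days). Beta-1,3-glucanase, an enzyme that degrades fungal walls, fell (-5.74 ± 0.80), as did xyloglucan endotransglycosylase 1 (-5.61 ± 0.74, above background on 2 of 3 arrays at 45 days) and a homeodomain protein of the antennapedia class (-5.64 ± 1.14). In all, 16661 probes passed, 7723 higher and 8938 lower, and 7905 changed at least 2-fold. With slide as a block 6634 passed, and 19 of the 20 named genes did, the homeodomain protein being at adjusted p = 0.0654. No slide held both ages of a genotype, so no value within a slide exists for age. The age effect with slide as a block rests on transgenic 45-day arrays as well, and is no comparison of control arrays alone.

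Camera called 6 lists for age in control leaves, 5 up and 1 down, with 0 called with an estimated correlation. Cellulose and arabinogalactan genes had 36 higher and 7 lower of 69 (median 0.60, adjusted p = 0.000494; adjusted p = 0.74 with an estimated correlation), cell cycle genes 39 higher and 11 lower of 74 (0.63, adjusted p = 0.000392; adjusted p = 0.712 with an estimated correlation), and tubulin and actin genes 26 higher and 2 lower of 63 (0.44, adjusted p = 0.000494; adjusted p = 0.712 with an estimated correlation). Lipid genes had 40 higher and 13 lower of 78 (0.64, adjusted p = 0.000494; adjusted p = 0.712 with an estimated correlation), and wall loosening genes 16 higher and 6 lower of 39 (0.73, adjusted p = 0.0316; adjusted p = 0.738 with an estimated correlation). Circadian genes had 0 higher and 9 lower of 10 (median -0.68, adjusted p = 0.00159; adjusted p = 0.684 with an estimated correlation). All 6 were called with slide as a block, whereas the wall loosening call was lost with a filter of all 12 arrays, with whole descriptions, and without control 45-day replicate 1 or 2. Adjusted over the list alone, the counts were the same except for 12 lower cell cycle genes and 41 higher lipid genes. By fry 13 lists were called. Median, mean and test differed in sign for the gossypol, chaperone, auxin, redox and senescence lists. The harvest hour is not given in the sources used here.

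Transgenic leaves changed with age to a similar extent, with 17233 probes passing, 8257 higher and 8976 lower, and 8507 changing at least 2-fold. The glycine-rich protein was at least 126-fold higher at 45 days, D6-type cyclin at least 20.8-fold and the MADS-box protein at least 7.94-fold. CP29.3 rose by 7.69 ± 0.39, L-asparaginase by 5.70 ± 0.32, the wall protein HyPRP1, with 2 of 3 arrays above background at 25 days, by 5.46 ± 0.73 and the thaumatin-like protein, with 1 of 3 arrays above background at 25 days, by 4.84 ± 0.68. The transporter P-glycoprotein CMDR1 rose by 4.85 ± 0.39, a serine protease-like protein, with 1 of 3 arrays above background at 25 days, by 4.92 ± 0.41 and a probe named for stage V sporulation protein AA by 4.94 ± 0.42. The osmotin-like protein fell (-10.19 ± 0.53), as did beta-1,3-glucanase (-8.68 ± 0.80, above background on 2 of 3 arrays at 45 days) and the hybrid proline-rich protein (-7.26 ± 0.30), while pod3 was at least 189-fold lower, pathogenesis-related protein class 10 at least 156-fold and xyloglucan endotransglycosylase 1 at least 39.2-fold.

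The non-symbiotic hemoglobin was at least 69.8-fold lower in 45-day transgenic leaves than in 25-day ones. Falls were also found for (+)-delta-cadinene synthase (-7.44 ± 0.74), the cell wall glycine-rich protein (-7.11 ± 0.51) and a trypsin inhibitor (-6.81 ± 1.05), each above background on 1 of 3 arrays at 45 days. With slide as a block 7235 probes passed, and 19 of the 20 named genes did, the trypsin inhibitor being at adjusted p = 0.0632. Camera called 5 lists, 3 up and 2 down, and 0 with an estimated correlation, while fry called 17. Cellulose and arabinogalactan genes had 41 higher and 9 lower (median 0.93, adjusted p = 1.91e-05), cell cycle genes 35 higher and 14 lower (0.56, adjusted p = 0.00908) and lipid genes 38 higher and 13 lower (0.55, adjusted p = 0.00691), each at adjusted p = 0.738 with an estimated correlation. Circadian genes had 0 higher and 8 lower (-0.46, adjusted p = 0.0129; adjusted p = 0.682 with an estimated correlation). Ribosomal proteins had 10 higher and 76 lower of 117 (median -0.81, adjusted p = 4.36e-07; adjusted p = 0.738 with an estimated correlation), whereas in control leaves 20 were higher and 20 lower (median -0.11, adjusted p = 0.97). The cell cycle call was lost with slide as a block (adjusted p = 0.125), and the cell cycle and circadian calls with a filter of all 12 arrays and in the deposited values. Adjusted over the list alone 44 cellulose, 37 cell cycle and 38 lipid genes were higher, 8 circadian genes were lower and 80 ribosomal probes were lower. Median, mean and test differed in sign for the gossypol, photosynthetic and fibre lists.

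**Figure D4:**
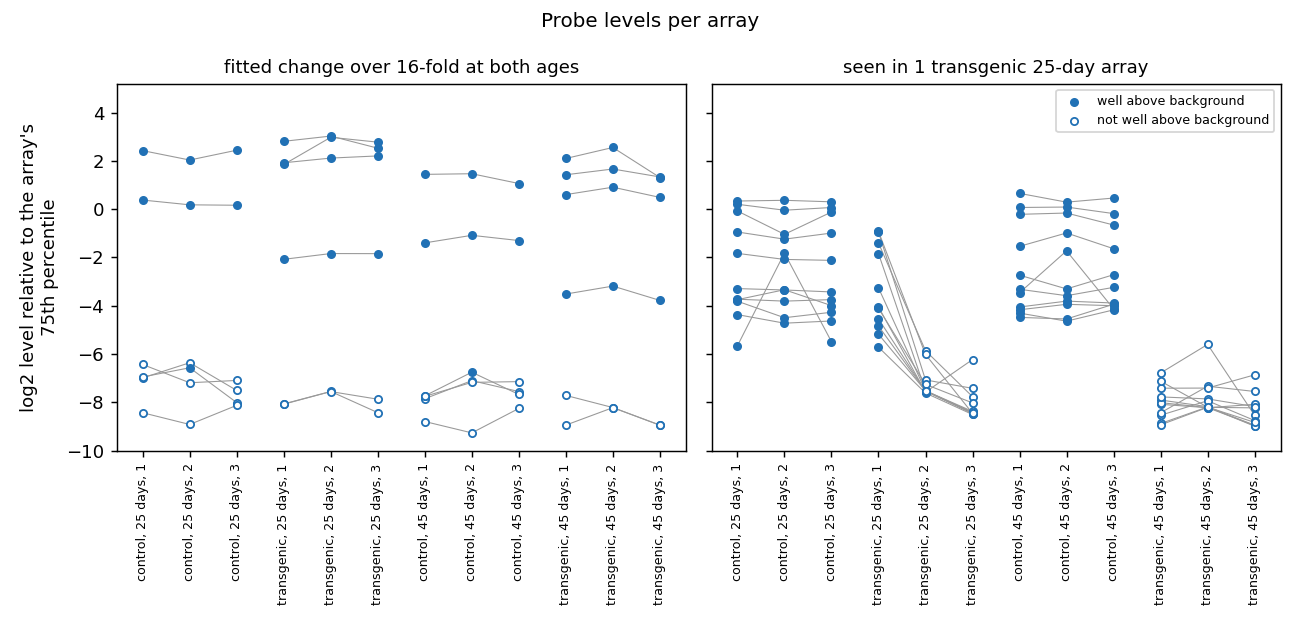
Log2 level relative to each array's 75th percentile (vertical axis) on each of the 12 arrays (horizontal axis). The left panel shows 6 probes that passed at both ages with fitted changes over 16-fold the same way. The right panel shows 11 probes seen in 1 transgenic 25-day array, some of which also fell over 16-fold on average at both ages. Lines join a probe's points within a group, and open points mark arrays not well above background. On the left, 4 probes are brighter in transgenic and 2 in control arrays, and on the right the transgenic signal is on replicate 1.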

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

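The gene list tests with slide as a block were chosen after the result was seen. The 6 gene lists below differed between the ages in their transgenic effect, by a test of the difference itself. The effect at 45 days lay below that at 25 days for ribosomal proteins (adjusted p = 3.66e-17), chaperones (adjusted p = 4.80e-05), tubulin and actin (adjusted p = 0.0146), cell cycle (adjusted p = 0.0440) and redox enzymes (adjusted p = 0.0486). It lay above for starch and sucrose (adjusted p = 0.0121), and none of the 6 passed with an estimated correlation or by fry.

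Lists were called as often under other groupings of the same arrays. For the difference between ages, 52 of 100 drawn regroupings of genotype within each age, from 200 possible, called at least the 6 lists found, the highest of the others calling 17, so chance is not excluded for the number of lists called. At 45 days, 9 of the 10 splits of the 6 arrays, the real one included, gave at least 5 lists, and the highest other split gave 12. At 25 days the real split called 0 lists, which every split reaches by definition, and the highest other split gave 10. For age, 7 of 10 splits gave at least 6 lists in control leaves, the highest other 10, and 8 of 10 gave at least 5 in transgenic leaves, the highest other 9. With 10 splits no share can lie under 0.05. Camera was run with a fixed correlation of 0.01 between members, whereas the correlation estimated from the replicates was 0.41 for ribosomal proteins and 0.53 for plastid-encoded transcripts, and with estimated correlations 0 lists were called in every comparison. Why other splits called so many lists was not tested.

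Ribosomal protein probes were lower in transgenic leaves at 45 days, with a median log2 fold change of -0.70 over 117 probes. The tables argue against the slide as the whole cause, since the median within slide 1 was -0.74, though with 1 transgenic array. They argue against a signal intensity trend, since the median over all arrays lay below 100% of 10000 random lists matched on mean signal. The lowest median of those lists was -0.18. They argue against the scaling of the arrays, since the median closest to 0 under other scalings and in the deposited values was -0.61. Other splits of the 45-day arrays gave medians from -0.34 to 0.45, and 10 splits are too few for a share under 0.05. The inserted domain may lower these transcripts, a hypothesis that these data leave open together with a shared difference of the sampled leaves, such as their growth stage, which was not tested. With a correlation between members estimated from the replicates, the list was at adjusted p = 0.794.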

How the results depend on the processing

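Gene list tests on whole descriptions and with slide as a block were chosen after the data were seen; the other tests here were not. Values within slide 3 at 25 days and within slide 1 at 45 days reuse 4 of the 6 compared arrays and are no independent check. Counts of probes and lists not given below stayed within 1.5 times, and the cause of changes was not tested except where fewer arrays or probes entered. Dim probes limit what can be said: surrogate signals below background give bounds, and with normexp the median of all probes at 45 days was 0.24, so its changes are relative to that. No scaling moved the share of higher calls by over 10 percentage points. A lone array of a group within a slide was assumed to vary like the other groups.

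At 25 days, where 50 probes passed, array weights gave 2494 (transgenic replicate 2 had a weight of 7.52), slide as a block 12 and scan as a block 12. Leaving out each replicate gave 18 to 154: 18 without transgenic replicate 3, 19 without control replicate 1 or 3, and 154 without transgenic replicate 1. At 45 days, where 4094 passed, a 2-fold minimum gave 701, normexp 2726, the 45-day arrays alone 276, and slide or scan as a block 132 each. Leaving out each replicate gave 675 to 4253, with 675 without transgenic replicate 1 and 2122 without control replicate 3.

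For the difference between the ages, where 0 passed, normexp gave 30, quantile normalization 747, a filter of all 12 arrays 498, the deposited values 763, no intensity trend 1, array weights 4440, and slide or scan as a block 8 each. Leaving out each replicate gave 0 to 1481: 1481 without control 45-day replicate 1, 860 without transgenic 45-day replicate 3, 17 without transgenic 45-day replicate 2, and 1 without control 45-day replicate 3 or transgenic 25-day replicate 1. Fits of the compared groups alone give no value for this difference. For age in control leaves, a 2-fold minimum gave 7905, normexp 11021, slide as a block 6634 and scan as a block 6640, and left-out replicates 14421 to 16364. For age in transgenic leaves, a 2-fold minimum gave 8507, slide or scan as a block 7235 each, and left-out replicates 15132 to 15909.

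The correlation of the effects at both ages, 0.143, was 0.180 with normexp, 0.104 without a filter, 0.0148 with a filter of all 12 arrays, 0.0264 in the deposited values, 0.0817 with array weights, and 0.0552 and 0.0554 with slide and scan as a block. Left-out replicates gave 0.0997 (without transgenic 45-day replicate 3) to 0.189 (without transgenic 45-day replicate 1).

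Called gene lists at 25 days were 2 with a filter of all 12 arrays and 0 to 7 over left-out replicates: 7 without transgenic replicate 1, 3 without control replicate 2 or transgenic replicate 3. At 45 days they were 0 with an estimated correlation, 3 by fry and 4 to 8 over left-out replicates, with 8 without transgenic replicate 3. For the difference between ages they were 0 with an estimated correlation and by fry, 3 with quantile normalization, 2 without a filter, 2 in the deposited values, and 3 (without control 45-day replicate 3) to 8 over left-out replicates. For age in control leaves they were 0 with an estimated correlation, 13 by fry and 5 to 8 over left-out replicates. For age in transgenic leaves they were 0 with an estimated correlation, 17 by fry, 3 with a filter of all 12 arrays, 3 in the deposited values, and 5 to 8 over left-out replicates, with 8 without replicate 3 of either age. Whole descriptions gave 0, 7, 5, 5 and 5 lists, and slide as a block 0, 5, 5, 8 and 4, in the order of the comparisons.

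Of the 88 probes named at 45 days, 3 were above 0 under normexp, alcohol dehydrogenase 2b at 0.19, laccase at 0.0867 and ribosomal protein S28 at 0.40, none of them passing there. Against the normexp median of 0.24, the first 2 lay slightly lower and S28 higher, so normexp showed no clear fall at any of the 3. All 3 were above background on at most 1 of 3 transgenic arrays. Of the 88, 52 still passed with normexp, 85 with quantile normalization, 11 with the 45-day arrays alone, 5 with slide as a block and 22 without transgenic replicate 1.

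Arrays with the same replicate number did not deviate together, with correlations from -0.27 to 0.20 over the 6 pairs of control and transgenic arrays. Whether the numbers pair the samples is not given in the labels. A replicate block gave 22 probes at 25 days, 1665 at 45 days, 0 for the difference between ages, 15911 for age in control leaves and 16525 in transgenic leaves.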

Other observations

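The tests of slide, background subtraction, the inserted construct, mixed-in control RNA and detection were chosen after the patterns were seen. By fry, several gene lists that camera did not call over all arrays moved with leaf age in both genotypes. Fry does not compare a list with other probes, so its calls do not show that a list stood apart from them. Of all tested probes, 53.4% passed for age in control leaves and 55.3% in transgenic leaves. Nutrition genes were lower at 45 days in control leaves (10 of 19 lower and 2 higher, median -1.09, adjusted p = 0.000181 by fry) and in transgenic leaves (10 lower and 2 higher, -0.91, adjusted p = 0.000109). Ethylene genes were lower on balance (16 of 38 lower and 7 higher, -0.53, adjusted p = 0.00211 in control leaves; 15 lower and 7 higher, -0.27, adjusted p = 0.000457 in transgenic leaves), as were RNA-binding genes (17 of 33 lower and 4 higher, -0.47, adjusted p = 0.000288; 15 lower and 3 higher, -0.39, adjusted p = 1.97e-05). Jasmonate genes were lower (12 of 26 lower and 5 higher, -0.37, adjusted p = 0.00939 in control leaves, and 10 lower and 5 higher, -0.39, adjusted p = 0.0241 in transgenic leaves), and so were flowering regulators (8 of 18 lower and 5 higher, -0.41, adjusted p = 0.0250, and 10 lower and 4 higher, -0.47, adjusted p = 0.0364). Gibberellin and brassinosteroid genes were higher (11 of 23 higher and 5 lower, 0.52, adjusted p = 0.00139 in control leaves, and 12 higher and 5 lower, 0.58, adjusted p = 0.000457 in transgenic leaves).

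Other lists passed by fry in 1 genotype, which is no test of a difference between the genotypes. In transgenic leaves, chaperones were lower with age (27 of 55 lower and 7 higher, median -0.43, adjusted p = 0.0144 by fry, against 0.996 in control leaves), as were lignin genes (15 of 34 lower and 5 higher, -0.42, adjusted p = 0.0287, against 0.278) and defence genes (13 of 31 lower and 6 higher, -0.18, adjusted p = 0.00627, against 0.0524). Auxin genes were higher there (9 of 21 higher and 2 lower, 0.45, adjusted p = 0.0119, against 0.588). In control leaves, starch and sucrose genes were lower (21 of 53 lower and 13 higher, -0.17, adjusted p = 0.00509, against 0.147 in transgenic leaves). With slide as a block, camera at the preset correlation did call the gibberellin and brassinosteroid list (median 1.05, adjusted p = 0.0232) and the nutrition list (-1.07, adjusted p = 0.0232) in control leaves. In transgenic leaves both were at adjusted p = 0.0946. The block joins the control ages through transgenic 45-day arrays, so these 2 calls are no comparison of control arrays alone. Without the block, the gibberellin and brassinosteroid median in control leaves was 0.52. With an estimated correlation over all arrays, camera called neither list in either genotype.

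At 6 probes that passed at both ages, the fitted change between genotypes was over 16-fold in the same direction, with surrogate signals on dim arrays. Of the 6, 4 were brighter and 2 dimmer in transgenic leaves, and 1, Wsv453, names a product. Further probes fell over 16-fold at both ages on average without passing at both, and some are described below for transgenic 25-day replicate 1. Of 100 drawn regroupings, 1, the real one, gave 6 such probes and the highest other gave 0. A call at 25 days was required, and other splits of the 25-day arrays called at most 2 probes. A regrouping that broke the 25-day split could therefore hardly reach 6, and no conclusion on chance is drawn. The tables argue against background subtraction, by unsubtracted signals at least 4.06-fold apart between the dimmest bright and the brightest dim array. At A_08_P347737 the bound on the log2 fold within slide 1 was 2.99, under the 4 asked for. The other 5 probes lay at 5.54 or more within slides 1 and 3. Each slide held both genotypes, and at all 6 probes the genotypes lay apart on each slide. Transgenic levels at A_08_P347737 were -3.51 on slide 1, -3.18 and -3.78 on slide 2, and -2.08 to -1.84 on slide 3. Control levels there were -8.12 or lower. These values argue against the slide as the whole cause, although the limit of 4 was missed at that probe. RNA from the inserted construct binding a probe could only add signal in transgenic leaves. The 2 falling probes, with a fall of at least -5.22, were above background on 6 control and 0 transgenic arrays. Added signal cannot produce a fall, but these 2 were chosen for their fall, so this is no test of the construct. They say nothing on the 4 rising probes. For the rising probes the construct was left open, since they were not compared with its sequence. For all 6 a candidate explanation is a difference in sequence or expression between the plant lines that is unrelated to the domain, which was not tested.

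Transgenic 25-day replicate 1 carried signal at 11 probes that were above background on all 6 control arrays and on none of the other 5 transgenic arrays, at a median of 50.5% of the control level (log2 difference -0.99, SD 0.38). Of 13 probes seen on all control arrays, on no transgenic 45-day array and on 1 transgenic 25-day array, 11 were on replicate 1, 0 on replicate 2 and 2 on replicate 3. Control RNA mixed into that sample would raise every probe bright in controls and off in the other transgenic arrays. It is argued against by the 2 probes that passed as over 16-fold lower at both ages. They lay at least 5.08 log2 units further below control there than the median of the 11, with that array's lowest signal well above background as their level. Their selection left out probes raised on that array, so they do not show how many probes stayed off there. More frequent detection on that array is argued against, since it supplied 12.1% of such lone detections at 215 probes that were on in 45-day transgenic leaves. A difference among the transgenic plants sampled, such as a segregating cotton sequence, may account for this pattern, but no biological explanation was tested.

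For the counts of probes passing, 1 of the 10 splits of the 6 arrays, the real one, gave as many in each comparison, and 10 splits are too few for a share under 0.05. The real and the highest other values were 50 and 2 at 25 days, 4094 and 142 at 45 days, 16661 and 0 for age in control leaves, and 17233 and 0 for age in transgenic leaves. For the difference between ages, 0 probes were found, which all 100 regroupings reach by definition, so that share says nothing on chance. Of the regroupings, 14 gave more than 0 and the highest gave 772. That highest one kept the real split of the arrays at both ages with the labels exchanged at 1 of them, so it holds the genotype effect, and the 10 of the 14 that kept the real split at neither age gave at most 14 probes. The correlation of the effects at both ages, 0.143, was reached in 8 of 100 regroupings, the highest at 0.245, so chance is not excluded for it.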
